A study of Homo sapiens with 14 samples.

How the data were processed

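GLORI libraries of polyadenylated RNA were examined from 6 cancer cell lines with DMSO (the ovarian lines CAOV3, COV644, EFO21 and SKOV3, with A549 and OE21) and from CAOV3 with 1 uM STM3675, 2 per group and 14 in all. Per the labels' protocols, RNA was fragmented, treated with glyoxal and nitrite and sequenced from small RNA libraries; spike-in probes of known methylation were added but were not analysed here. Adapters were trimmed with cutadapt and reads aligned with STAR to GRCh38, per the submitters' processing notes; versions, mapping settings and the site caller are not given in the sources used here. The authors deposited counts of reads with A or G per site and library, and the fraction of those reads that are A. The fraction times the count came out whole within 1e-06 for every site, so A and G counts were recovered exactly. The counts reach 10040 at most, as if depth had been capped, which touches 0.0013% of values. Each row of the deposited table has 1 site in 1 cell line, with DMSO and treated columns; the column names starting with D and T were read as DMSO and treated. The table held 2451078 rows, that is 408513 for each cell line, with 407343 unique sites; 469 sites stand under more than 1 gene and were used once in tests of sites. All sites passed a minimum of 20 reads and a fraction of 0.25 in at least 1 DMSO library, and 0 in an STM3675 library only. Exactly 1 DMSO library passed at 277706 sites (68.2%). Gene, exon and 5-base motif are those of the table; 54110 sites (13.3%) have no gene, and coding or untranslated parts were not used here.

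Sites were tested where every library compared had at least 20 reads, a minimum set before the data were examined. A logistic model with quasi-binomial dispersion was fitted per site in R 4.3.3, the Pearson dispersion was moderated over sites with squeezeVar of limma 3.58.1 and floored at 1, and F tests were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The moderation gave all sites 1 common dispersion, 1.67 in CAOV3 and 1.71 over the lines, so sites with more spread than others are called too readily. Taken by line with DMSO, the dispersion was 2.74 in SKOV3, 2.03 in EFO21, 1.98 in CAOV3, 1.69 in A549, 1.31 in COV644 and 1.23 in OE21. Differences of a line above the common value are thus called too readily, and those of a line below it too rarely. For genes, A and G counts were summed over tested sites. Lists fixed beforehand were compared with other genes by limma's camera with a preset correlation of 0.01, if 5 or more members were measured, which 10 of 13 lists met. Lines were compared as a factor of 6 levels over 12 DMSO libraries, and each line with the mean of the other 5. Mean levels were compared by permutation over 1e+05 resamples, and CAOV3 means by an exact permutation test. Tables and figures used the R package data.table, version 1.17.8, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

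The method was tested on simulated data. With 200 of 185923 sites changed in the CAOV3 design, 18% of 100 sites lowered to 0.5 of their level and 36% of 100 lowered to 0.25 were recovered, and 0 unchanged sites were called. With the sites that fell in the data set to their observed levels, 92.9% of them were recovered, and 891 and 872 unchanged sites were called higher and lower. Those lowered sites had already passed the same test, so 92.9% is not its sensitivity. Over 68873 sites in 6 lines, 52% of 200 sites lowered to 0.5 in 1 line were recovered by the test over all lines and 59% by the test of 1 line against 5. As a check of real data, the replicate number called 3 of 68873 sites over the 12 DMSO libraries. Replicates differed by more than counting noise, with a chi-square per degree of freedom of their read counts between 3.7 and 20.3, so none were merged.

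Total reads at these sites ran from 14047302 to 28663588 per library. The deposited counts do not tell whether duplicate reads were merged by molecular identifiers. Reads may thus not be independent molecules, and the counting part of each error is to be taken as a lower limit. Genes and sites were named by rules fixed before the data were examined: the 10 largest falls and up to 10 largest rises among called sites with 50 reads per library and no overlap between groups, 1 per gene; the 5 highest ratios among sites at 0.5 or more with DMSO; MAT2A, METTL3, METTL14, MYC, MALAT1, ADAR and EIF2AK2; 2 members with the most and 2 with the least negative difference of each list; the 12 sites with the largest range among lines, out of called sites with 50 reads per library and no overlap between the highest and lowest line, 1 per gene; and, for each line, the 1 higher and 1 lower site with the largest difference from the mean of the other 5 among sites called for that line, 1 per gene and without the genes of those 12 sites. MALAT1 was not analysed here. Of the items these rules gave, 2 are not reported here. The sites at the start of first exons, FTL and the genes that rose were named after their values were seen.

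Alternatives fixed beforehand were a minimum of 50 reads, each library left out, the replicate number as a block, limma on log2((A+0.5)/(G+0.5)), a minimum difference of 0.1, all 14 libraries in one fit, Fisher's exact test on pooled counts, DRACH sites only (for sites and mean levels), weighted means, unweighted gene means and an estimated correlation. Added after the data were seen were sites that passed in another line, a dispersion trend on coverage, the one-sided test, subtraction of each library's non-DRACH median or of the STM3675 mean of the lowest DRACH class, DRACH sites only for genes and gene lists, the trend on the DMSO level, DRACH sites of 0.25 or more among lines, and the split of lines by a non-DRACH median of 0.05. With a library left out, the lone library of a group was assumed to vary like the others. The common dispersion then came only from the groups left whole, so counts of calls also move with the spread of those groups.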

Results

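N6-methyladenosine (m6A) was measured at single adenosines with GLORI, in which glyoxal and nitrite deaminate unmethylated adenosines so that they are read as G, while methylated adenosines are still read as A. Polyadenylated RNA came from 6 human cancer cell lines kept in the solvent DMSO for 24 h: A549 (lung carcinoma), CAOV3, COV644, EFO21 and SKOV3 (ovarian) and OE21 (oesophageal), with 2 libraries per line. CAOV3 cells were also exposed to 1 uM STM3675 for 24 h, again with 2 libraries. The series concerns inhibition of METTL3, the catalytic subunit of the main m6A methyltransferase of messenger RNA. The deposited table lists 407343 adenosines of GRCh38, of which 156317 (38.4%) lie in DRACH, the sequence motif that METTL3 methylates. Each library had between 14047302 (EFO21 replicate 2) and 28663588 (CAOV3 STM3675 replicate 1) reads with A or G at these sites, and a median of 16 to 32 reads per site. The m6A level of a site is the percentage of those reads that are A. Values are means ± SD of 2 libraries unless stated otherwise. The labels do not say whether the replicates were separate cultures, so p-values speak only of these libraries, whose spread may be technical. At single sites the quasi-binomial p-values rest on read counts and 1 dispersion common to all sites. A site's own spread between libraries has no weight in them.

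The first comparison asks how far STM3675 lowered m6A in CAOV3. DRACH sites lost most of their m6A: their mean level was 45.4% ± 0.78 with DMSO and 11% ± 0.097 with STM3675, and 56935 of the 77040 tested DRACH sites (73.9%) fell. Among DRACH sites at 50% or more with DMSO, 29030 of 29059 fell, from a mean of 77.6% ± 0.7 to 14.4% ± 0.15. Sites outside DRACH, whose median with DMSO was 11.9%, went from a mean of 13.9% ± 0.16 to 9.97% ± 0.028, and 8568 of 108883 fell. Of those at 25% or more with DMSO 5346 of 7937 fell (67.4%), from 40.7% ± 0.23 to 12.5% ± 0.17. Over all 185923 tested sites 65503 fell and 574 rose, by a quasi-binomial model with Benjamini-Hochberg adjustment. The mean level with STM3675 was 0.386 ± 0.0063 of that with DMSO over all tested sites and 0.242 over DRACH sites. The libraries did not overlap (26.6% and 27.2% with DMSO, 10.3% and 10.4% with STM3675), and the two-sided exact permutation p of 0.333 is the smallest that 6 splits allow for 2 against 2. As a measure of unconverted adenosine, the median of non-DRACH sites listed because of another line was 9.38% and 9.59% in the DMSO libraries and 9.09% in each STM3675 library. After that median was subtracted from DRACH sites listed because of another line, 0.0558 of the DMSO level was left, and 0.0821 after the STM3675 mean of DRACH sites under 10% in the other lines (7.95%) was subtracted instead, both choices made after the data were seen.

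The 10 sites with the largest falls, 1 per gene, went from nearly complete methylation to under 10%, and 9 of them lie in the last exon. DIRAS3, which encodes a Ras-family GTPase, had 98.3% ± 0.012 with DMSO and 7.72% ± 0.6 with STM3675 at position 68046502 of chromosome 1 (last exon 2, GGACT; 589 to 1140 reads per library). A site of UHRF1, a factor of maintenance DNA methylation, at 4961398 of chromosome 19 (last exon 17) fell from 96% ± 1.1 to 6.11% ± 1.1 (adjusted p = 5.1e-47). ATG5, which acts in autophagosome formation, fell from 97.9% ± 1.6 to 6.22% ± 0.55 at 106186164 of chromosome 6 (last exon 8). In SOCS6, of the suppressor of cytokine signalling family, the site at 70324772 of chromosome 18 fell from 97.1% ± 1.4 to 7.16% ± 2. CFAP97 at 185190935 of chromosome 4 (internal exon 2) had the largest difference of all, -92.1 percentage points. Further sites were in ZBTB14, EVA1C, SERTAD1 and GEMIN6, with differences of -90.8, -90.5, -89.9 and -89.7 points.

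By position in the gene, 81.7% of tested DRACH sites in last exons fell (38704 of 47365, mean 49.1% to 10.9%) and 88.8% of those in single-exon genes (1647 of 1855, 60% to 14.2%). In internal exons 56.6% fell (10978 of 19389), from a lower starting mean of 37%, and in first exons 55.5% (1282 of 2311). By motif, GGACT had the highest DMSO level, 59.3%, and was at 13.4% with STM3675. GAACT was at 52.9% and 9.46%, and TAACC, the lowest, at 15% and 6.38%. When DRACH sites were classed by their level in the other 5 lines, the STM3675 mean was 8.37% ± 0.017 for sites at 25% to 50%, 9.94% ± 0.079 for 50% to 75%, 13.3% ± 0.18 for 75% to 90% and 23.6% ± 0.16 for 90% or more. The last class had been at 96.2% ± 0.2 with DMSO. In these 4 classes the STM3675 mean was 0.199, 0.146, 0.153 and 0.246 of the DMSO mean, and 0.251, 0.172, 0.182 and 0.281 at non-DRACH sites of the same classes.

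**Figure D1:**
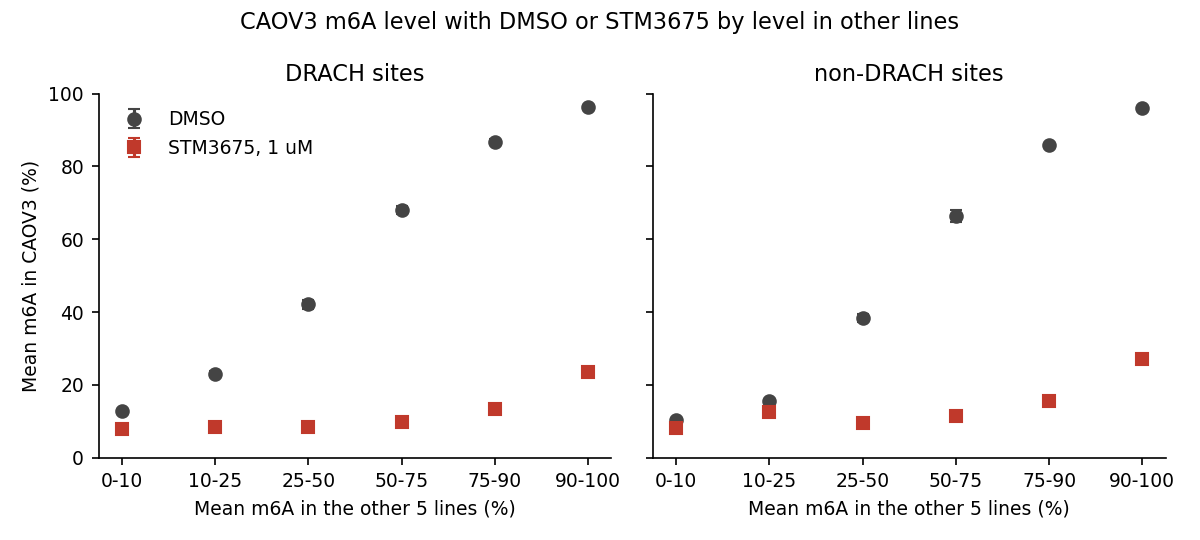
Mean m6A level in percent in CAOV3 (vertical axis) with DMSO and with STM3675, for sites classed by their mean level in the other 5 lines in percent (horizontal axis), with DRACH and non-DRACH sites apart and error bars of 1 SD of 2 libraries. DRACH sites at 90% to 100% in the other lines were at 96.2% with DMSO and 23.6% with STM3675.

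Rises were few. The 10 largest, in SLC38A10, LUC7L2, WDR61, MYH9, CCHCR1, TTC3, UPF1, LSS, BAIAP2L1 and MMUT, lie outside DRACH. SLC38A10 at 81294827 of chromosome 17 (first exon) had 41.7% ± 3.8 with DMSO and 59.1% ± 0.82 with STM3675 (adjusted p = 8.2e-07, 251 to 762 reads). At the sites of UPF1, a helicase of nonsense-mediated decay, and MYH9, a nonmuscle myosin, the levels were 2.42% ± 3.4 against 18.2% ± 6.1 and 8.16% ± 4 against 24.5% ± 5.8. In simulated data with as many lowered sites, 891 unchanged sites were called higher, so 574 calls are no more than errors of the test can give, and 8 of the 10 named rises lose the call with limma. The count went up without either DMSO library and down without either STM3675 library. With 1 library left out, the common dispersion comes only from the pair left whole, 1.39 for STM3675 and 1.98 for DMSO. The swings go the way this setting would move them. A one-sided test added after the data were seen left 3 sites: SLC38A10, MAT2A at 85543815 of chromosome 2, and FTL, the ferritin light chain, at 48966405 of chromosome 19 (18.3% ± 3.3 and 26.3% ± 1.4, 10002 to 10012 reads, where the table's depth appears capped).

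MAT2A, which encodes the S-adenosylmethionine synthetase subunit and whose last exon holds sites methylated by METTL16, had falls at its DRACH sites and none at its METTL16-type sites. The DRACH sites fell: position 85542602 (internal exon 7) from 25.7% ± 0.098 to 7.63% ± 1.9, and 85543704 (last exon 9) from 26.7% ± 0.81 to 7.79% ± 1.6. Of the 6 ACAGA sites in the last exon, 0 fell and 1 rose, with a mean of 36.3% with DMSO and 43.3% with STM3675. The 1 that rose, 85543815, had 52.1% ± 1.2 and 66.4% ± 1.9 (adjusted p = 1.5e-09, 695 to 980 reads). It kept its call with each library left out but not with limma. At the other 5 the adjusted p ran from 0.1 to 0.58, and 85544902 and 85545017 also passed as higher without DMSO replicate 1. ACAGA sites of other genes, 424 in all, had means of 10.3% and 8.33%. Over its 14 tested sites the gene was at 31.6% ± 1.1 and 29.5% ± 0.7 and did not pass over all genes (adjusted p = 0.055), while it passed as fallen adjusted over the list alone, a list of 1 gene, and without DMSO replicate 1. Its direction turned with the sites counted: over its sites that passed in another line it passed as higher.

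Of 16568 sites at 50% or more with DMSO and with 50 or more reads in every library, 29 kept over 0.8 of their level, against a median ratio of 0.152 (quartiles 0.12 and 0.201). The highest ratios were at MAT2A 85543815 (1.28), PMEPA1 57649648 of chromosome 20 (1.16), the histone gene H2BC12 at 27146855 of chromosome 6 (1.11), the chaperone gene HSP90AA1 at 102087044 of chromosome 14 (1.06) and a site with no gene at 94110736 of chromosome 14 (1.03). H2BC12 and HSP90AA1 belong to a group singled out after the values were seen: all 13 such sites within 10 nt of the start of a first or single exon were among the 29, with a median ratio of 0.965. HSP90AA1 had 75% ± 7.1 with DMSO and 79.1% ± 0.89 with STM3675, TUBB4B 89.2% ± 2.1 and 90.9% ± 3.8, and the metallothionein gene MT1E 74% ± 1.7 and 74.6% ± 1.4. The adjusted p at the 13 ran from 0.17 to 0.97, which does not show that the levels were equal.

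Summed per gene, m6A fell in 9104 of 11158 genes (81.6%) and in 9029 of the 10151 genes with a tested DRACH site (88.9%). The median difference was -20.1 percentage points. MYC, the growth-promoting transcription factor, fell from 61.4% ± 1.7 to 12.2% ± 0.61 (adjusted p = 1.2e-13). The 7 genes that rose, PHLDB3, NUDT17, FKBP11, MT1A, FTL, NDC80 and NXT2, were named because they are few, and had no tested DRACH site. Their number was 32 and 31 without DMSO replicates 1 and 2, and 3 and 1 without STM3675 replicates 1 and 2.

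Among m6A writers, erasers and readers 21 of 26 measured genes fell (21 adjusted over the list alone). The reader genes YTHDF2 and YTHDF1 fell from 70.1% ± 0.73 to 11.8% ± 0.53 and from 57.3% ± 2.4 to 10.1% ± 0.08. METTL14 fell from 52.9% ± 2.2 to 8.51% ± 1.5, and METTL3 from 26.4% ± 2.5 to 9.52% ± 1.5. HNRNPC fell from 15% ± 0.18 to 10.9% ± 0.16, a call lost with limma on unweighted means, and FMR1 was at 12.5% ± 2.5 and 11.1% ± 1.5 and did not pass. FMR1 had 2 DRACH sites among 19 tested. In double-stranded RNA sensing and editing 22 of 26 fell (22 adjusted over the list alone). They include OASL, of the oligoadenylate synthetase family (49.7% ± 1.6 to 9.16% ± 0.62), TARBP2 (50.2% ± 1.3 to 12% ± 0.13), the adenosine deaminase gene ADAR (39.5% ± 0.81 to 8.36% ± 0.085) and EIF2AK2, which encodes the kinase PKR (18.5% ± 0.41 to 7.16% ± 0.47). DHX9 (14.6% and 13%) and TBK1 (9.67% and 8.5%) did not pass, although TBK1 passed as fallen over sites with 50 reads. Each had 1 DRACH site, among 9 tested sites in DHX9 and 23 in TBK1. Of 54 interferon-stimulated genes 45 fell (45 adjusted over the list alone), among them TRIM21 (66.7% ± 0.11 to 9.22% ± 0.66) and IFIT2 (46.8% ± 5 to 8.5% ± 0.13). USP18 (9.67% and 9.12%) and IFITM3 (11.6% and 13.7%) did not pass, and IFITM3 passed as higher without DMSO replicate 2 or STM3675 replicate 1. IFITM3 had no tested DRACH site, and USP18 had 2 among 7 tested sites.

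In antigen presentation 13 of 17 fell (13 adjusted over the list alone). The chaperone genes CALR and PDIA3 fell from 62.1% ± 1.5 to 16.2% ± 0.2 and from 62.7% ± 1.7 to 27.1% ± 0.94, while HLA-B (10.7% and 11.8%) did not pass. HLA-B shares sequence with related genes, so the assignment of its reads is uncertain, and it passed as higher without DMSO replicate 2, over sites with 50 reads and over sites that passed in another line. It had 3 DRACH sites among 18 tested. In cleavage, polyadenylation and termination 32 of 39 fell (32 adjusted over the list alone), such as INTS9 (59% ± 1.6 to 7.86% ± 1) and CSTF1 (57.6% ± 0.64 to 10.1% ± 0.002), but not XRN2 (7.84% and 8.99%) or CPSF3 (6.21% and 8.12%), which had no tested DRACH site. Of 36 splicing factors 27 fell (27 adjusted over the list alone), including SF3B3 (65.9% ± 0.28 to 10.7% ± 0.99) and SRSF5 (49.2% ± 1.5 to 9.63% ± 0.86). HNRNPA1 (11.2% and 11.4%) and SRSF7 (15.7% and 17.2%) did not pass. SRSF7 had no tested DRACH site, and HNRNPA1 had 2 among 12 tested sites. In nuclear RNA surveillance 24 of 29 fell (24 adjusted over the list alone), among them NCBP3 (55% ± 3.2 to 10.7% ± 0.89) and EXOSC3 (49.4% ± 1.5 to 7.95% ± 0.63), and not TRIM28 (17.2% and 15.4%) or SRRT (11.6% and 10.5%). Of 44 cell cycle genes and oncogenes 40 fell (40 adjusted over the list alone), including BCL2L1 (53.3% ± 2.5 to 11.8% ± 0.021), while CDKN2A (23.8% and 20.9%) and CCND3 (16.8% and 15.1%) did not pass. TRIM28 and CCND3 passed as fallen over their DRACH sites only, and CDKN2A without DMSO replicate 1.

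Ribosomal proteins and translation stood apart: 10 of 29 fell (9 adjusted over the list alone), with a median difference of -1.06 points. Their median level with DMSO was 19.4%, the lowest of the lists. A DRACH site was tested in 19 of them, 54 sites in all. RPL13A (68.8% ± 0.62 to 10.4% ± 0.6) and the elongation factor gene EEF1A1 (60.2% ± 0.26 to 6.25% ± 0.048) fell, while RPL19 (11.2% and 15.7%) and RPS18 (12.6% and 17.7%) did not pass, but passed as higher without DMSO replicate 1. RPS18 had no tested DRACH site and RPL19 had 1. Camera placed this list above the other genes, that is, with a smaller fall (adjusted p = 9e-10), but adjusted p = 0.18 with an estimated correlation. Camera gave adjusted p = 3.2e-05 over DRACH sites and 2.7e-07 relative to the trend on the DMSO level, both choices made after the data were seen. Among epithelial and lineage markers 9 of 16 fell (9 adjusted over the list alone), such as the tight-junction gene CLDN4 (67.4% ± 3.4 to 15.4% ± 0.35) and CD24 (59% ± 2.5 to 10.7% ± 0.25), but the keratin genes KRT8 (14% and 14.7%) and KRT18 (15.1% and 15.9%) did not pass. KRT8 had 2 DRACH sites among 9 tested, and KRT18 had 2 among 15. Camera gave adjusted p = 0.036 for this list, and adjusted p = 0.51 with an estimated correlation. It also missed the threshold without DMSO replicate 1 (adjusted p = 0.068) or replicate 2 (adjusted p = 0.09). None of the other 8 lists tested passed with camera, with adjusted p from 0.19 for cell cycle genes to 0.98. Nuclear long noncoding RNAs, MALAT1 among them, and mitochondrially encoded RNAs were not analysed here.

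The table lists only sites that reached a level of 25% in some DMSO library, so sites gained with STM3675 cannot be seen, and sites near that limit start high by selection. Among sites listed because of another line, which CAOV3 did not select, 58148 of 151345 fell, with means of 28.2% ± 0.45 and 10.5% ± 0.056.

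The second comparison asks how m6A differs among the 6 lines with DMSO. CAOV3 had the highest and OE21 the lowest level. At 25015 DRACH sites with a mean of 25% or more, covered in all 12 libraries, CAOV3 was at 63.2% ± 0.95, COV644 at 60.7% ± 0.72, EFO21 at 58.5% ± 0.22, A549 at 57.7% ± 0.095, SKOV3 at 57.1% ± 0.059 and OE21 at 55.3% ± 0.31. A permutation test of the variance between lines gave p = 1e-04, the smallest that these permutations can give. Over all 68873 covered sites the means were 33.7% ± 0.53 in CAOV3, 31.6% ± 1.1 in EFO21, 31.2% ± 1 in SKOV3, 30.4% ± 0.023 in A549, 28.9% ± 0.097 in COV644 and 26% ± 0.054 in OE21 (permutation p = 5e-04). The median of non-DRACH sites, taken here as a measure of unconverted adenosine, was 4.36% ± 0.73 in COV644 and 4.32% ± 0.17 in OE21 but 10.6% to 12.8% in the other 4 lines. With it subtracted, COV644 was highest (56.3% ± 1.5), followed by CAOV3 (52.2% ± 0.84), OE21 (51% ± 0.48), A549 (47.1% ± 0.13), EFO21 (46.1% ± 1.9) and SKOV3 (44.4% ± 2.2). Plain subtraction also takes background from methylated copies, which are read as A in any case. It thus lowers the 4 lines of higher background too much against COV644 and OE21. Within the 4 lines of higher background CAOV3 was highest either way, and of the 2 lines of lower background COV644 was above OE21 either way. A site is listed once 1 DMSO library reached 25%, and 51235 sites passed in OE21 replicate 1 but 119586 in SKOV3 replicate 2. These means and medians, and the counts per line below, include sites listed only through the line itself. Such sites were not removed, so each line may stand higher by selection.

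**Figure D2:**
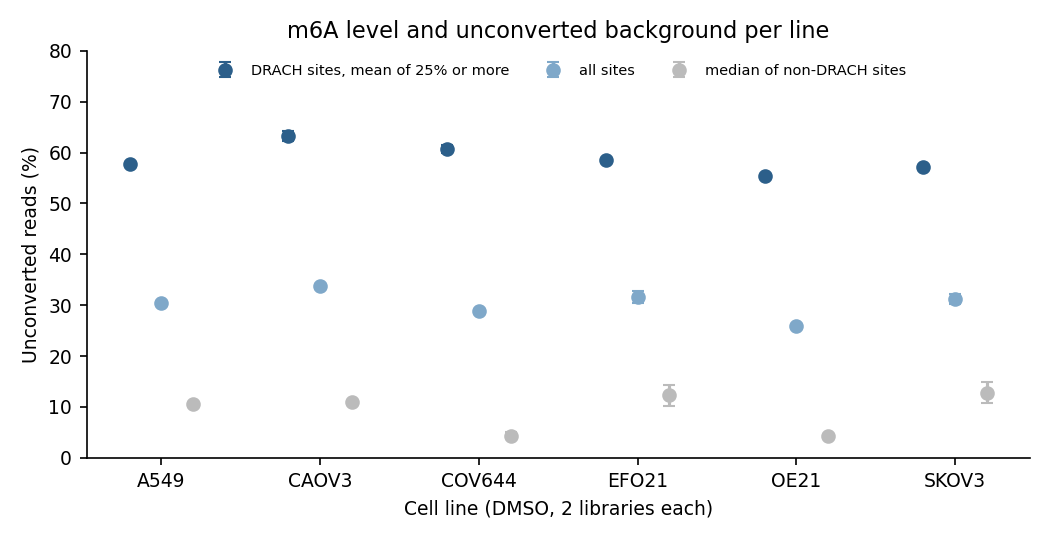
Unconverted reads in percent (vertical axis) in each cell line with DMSO (horizontal axis), as the mean of 2 libraries with error bars of 1 SD, for DRACH sites of 25% or more, all sites, and the median of non-DRACH sites. At the DRACH sites CAOV3 had 63.2% and OE21 55.3%, and the non-DRACH median was lowest in OE21 (4.32%) and COV644 (4.36%).

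Levels at single sites differed among lines at 27213 of 68873 sites (39.5%), and limma called 6688. Within the 4 lines of higher background 6871 sites differed, and 3170 differed between COV644 and OE21. The median range between the highest and lowest line was 19.3 points at called DRACH sites of 25% or more. Across sites, which are not independent replicates, Pearson's r was 0.926 to 0.953 between lines and 0.941 to 0.96 between replicates. Against the mean of the other 5 lines, CAOV3 was higher at 9866 sites and lower at 191, and OE21 was higher at 324 and lower at 4859. Without CAOV3 replicate 2, 6510 were higher, and without replicate 1, 85 were lower. OE21 was lower at 1381 and 1164 sites without its replicates 1 and 2, and higher at 139 and 97. At DRACH sites of 25% or more CAOV3 was higher at 5882 and lower at 220, and OE21 was higher at 374 and lower at 3862. None of these counts is corrected for background. All lines were tested with 1 common dispersion although their replicates spread unequally, so the counts of different lines cannot be compared directly. With background subtracted, the OE21 mean at these DRACH sites (51%) was above A549 (47.1%), EFO21 (46.1%) and SKOV3 (44.4%). It was below COV644 (56.3%) and CAOV3 (52.2%). Plain subtraction lowers A549, EFO21, SKOV3 and CAOV3 too much against OE21. COV644 was higher at 2662 sites and lower at 1940, or 2883 and 1019 at these DRACH sites. Without its replicates 1 and 2, COV644 was higher at 1137 and 867 sites and lower at 634 and 558. For the other 3 lines the balance turned with the choice of sites. A549 was higher at 1668 and lower at 1334 sites, but 969 and 1871 at these DRACH sites. EFO21 was higher at 3052 and lower at 1166, but 667 and 1229, and SKOV3 was higher at 4773 and lower at 1854, but 322 and 1853. Without their replicates 1 and 2, A549 was higher at 1002 and 1026 sites and lower at 468 and 564, and EFO21 was lower at 625 and 662. EFO21 and SKOV3 were higher at more sites without their replicate 1, and SKOV3 at fewer without its replicate 2. In both lines replicate 2 had the higher non-DRACH median, 13.8% against 10.8% in EFO21 and 14.3% against 11.3% in SKOV3, at sites covered in all 14 libraries. SKOV3 was lower at 897 sites without its replicate 2. Leaving out COV644 or OE21 libraries brought the sites higher in EFO21 down to 1483, without OE21 replicate 2, and those higher in SKOV3 to 2519, also without OE21 replicate 2. Without OE21 replicate 2, A549 was higher at 1071.

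The share of A reads at single sites ranged from nearly absent to nearly complete between lines. No genome sequence of these lines was used, so a low share need not mean lost methylation. In LAMC1, the laminin gamma 1 chain, position 183142907 of chromosome 1 (last exon 28, TGACT; 240 to 3158 reads) was at 93.5% ± 1.5 in CAOV3, 63.7% ± 0.86 in A549, 56% ± 2.3 in SKOV3, 40% ± 1 in COV644, 5.89% ± 0.53 in EFO21 and 2.59% ± 0.44 in OE21. EIF2B2, a subunit of the translation factor eIF2B, at 75009369 of chromosome 14 (last exon 8, GGACT) was at 90.7% ± 0.32 in COV644 and 90.4% ± 3 in EFO21 but at 9.37% ± 0.8 in CAOV3 and 7.51% ± 5.7 in OE21 (adjusted p = 2.3e-182). SKA3, of the spindle and kinetochore complex, at 21154926 of chromosome 13 (last exon 9) was at 86.6% ± 3.4 in CAOV3 and at 6.27% ± 0.35 in A549 and 4.1% ± 2.2 in OE21. In 3 genes EFO21 was apart: TMEM203 at 137204634 of chromosome 9 (10.5% ± 0.64, 75.2% to 93.6% in the others), FAM83D at 38952026 of chromosome 20 (4.37% ± 1.7, 62.7% to 81.8%) and ARHGEF39 at 35661828 of chromosome 9 (84.6% ± 6, 21.3% to 25.1%). DAG1, which encodes dystroglycan, was at 75.8% ± 2.1 in SKOV3 and 32% ± 1.9 in COV644 but at 4.92% to 9.06% in the other 4 lines, at 49533448 of chromosome 3. KIRREL1 (158096252 of chromosome 1) was at 65.2% ± 2.1 in CAOV3 and 0.505% ± 0.71 in A549. MARCHF7 was lowest in SKOV3 (16.2% ± 4.2) and TRABD in EFO21 (6.19% ± 2.6). The 2 sites with no gene, 121641533 of chromosome 12 and 40834760 of chromosome 17, ranged over 73 and 66.6 points.

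**Figure D3:**
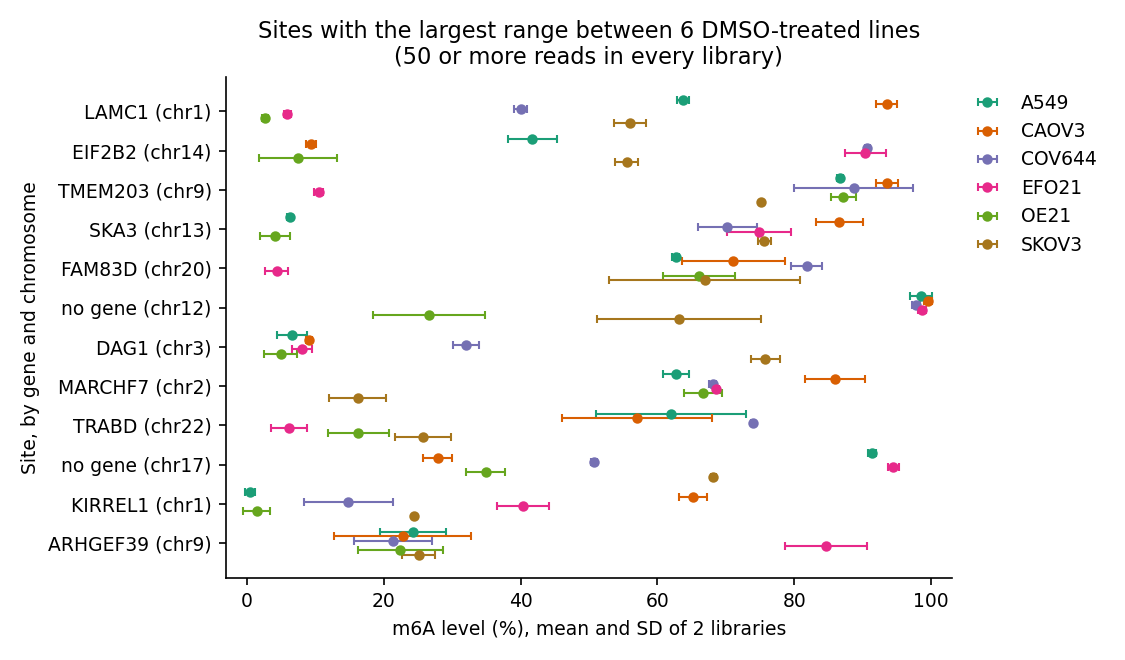
m6A level in percent (horizontal axis) at the 12 called sites with the largest range among lines (vertical axis, by gene and chromosome) out of those with 50 or more reads in every library and no overlap between the highest and lowest line, 1 per gene, with 1 point per line for the mean of 2 DMSO libraries and error bars of 1 SD. At LAMC1 the range was 90.9 points, from 2.59% in OE21 to 93.5% in CAOV3.

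Leaving out the genes named above, several of which differ more, the sites called for 1 line with the largest difference from the mean of the other 5 follow, 1 per gene. MED31, of the Mediator complex, was at 97.7% ± 3.2 in COV644 and at 5.95% over the other 5 lines (6644445 of chromosome 17; adjusted p = 2.4e-10). PGAP2 was at 1.91% ± 1.2 in OE21 against 81.2% (3826063 of chromosome 11; adjusted p = 1.3e-34), and BMT2 at 90.6% ± 5.6 in OE21 against 15.2%. KAT14 was at 77.5% ± 14 in EFO21 against 17%, and TOM1L2 at 19.8% ± 0.32 against 62.1%, although OE21 was lower there (9.08% ± 0.76). LATS1, a kinase of the Hippo pathway, was at 81.7% ± 8.2 in A549 against 25.8%, although OE21 had 88.3% ± 4.8, and SMUG1 at 14.6% ± 12 in A549 against 66.7%. GEMIN4 was at 96.1% ± 1 in CAOV3 against 43.9%, with EFO21 and SKOV3 at 95.5% and 96.3%, and LSG1 at 20.2% ± 4 against 77.3%, although OE21 had 17.9% ± 1. NUS1 was at 62.3% ± 4.1 in SKOV3 against 20.6%, with EFO21 at 61.2% ± 2.4, and a site with no gene at 36049891 of chromosome 20 at 33.8% ± 4 against 92.3%. SETDB1, a histone methyltransferase, was at 20.7% ± 19 in COV644 against 64.3%, with OE21 at 32.9% ± 21, and did not pass within the 4 lines of higher background or between the 2 of lower. Every one of these sites kept its call for its line with each library left out. MED31 and BMT2 did not pass within the 4 lines of higher background, nor did SMUG1, GEMIN4, KAT14, NUS1, the site at 36049891 and, of the sites in the paragraph before, TMEM203, FAM83D, MARCHF7 and ARHGEF39 between COV644 and OE21, comparisons that leave out the line for which each is named. The reads behind these sites went down to 20 per library, where a level is known only coarsely.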

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

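Tests on sites that passed in another line, DRACH sites only for genes and gene lists, one-sided rises, background subtraction, the trend on the DMSO level, a dispersion trend on coverage, DRACH sites of 0.25 or more and the split of lines by background were chosen only after the results were seen; the other alternatives were fixed before the data were examined. The count of genes that fell stayed within 1.5 times of 9104 under every alternative run. Of the results for single named sites, genes and line sites under alternatives, 366, 405 and 443 kept their direction and their side of the threshold, 32, 1 and 17 lost the call, 5, 16 and 0 gained one, and 11 site and 23 gene results changed direction. Together with gene lists there were 43 changes of direction, of which 0 concerned a result that had passed and 1 passed after the change: MAT2A as a gene. All 17 calls lost at line sites were within the 4 lines of higher background or between the 2 of lower background. The calls of single lines against the other 5 at named sites were kept in all 152 results under alternatives. The 10 named falls kept the call wherever measured. Of the 10 named rises 8 lost it with limma and 8 with some library left out, and MAT2A 85543815 lost it with limma.

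The changes of direction are given as differences of proportion, STM3675 minus DMSO. MAT2A as a gene was at 0.0691 over sites that passed in another line and 0.00681 with unweighted means. With 50 reads FMR1 was at 0.0371, USP18 at 0.00329 and CPSF3 at -0.0161. With unweighted means DHX9 was at 0.00023, HLA-B at -0.0065, HNRNPA1 at -0.00979 and SRSF7 at -0.0358. Over DRACH sites FMR1 was at 0.0178, HLA-B at -0.00145, HNRNPA1 at -0.0438 and SRRT at 0.0193, and over sites that passed in another line FMR1 was at 0.0144, TBK1 at 0.000276 and USP18 at 0.00329. With 1 library left out, the values ran from -0.0319 to 0.00374 for FMR1 (0.00374 without DMSO replicate 1), -0.0205 to 0.00363 for USP18 (0.00335 without STM3675 replicate 1, 0.00363 without DMSO replicate 2), -0.0112 to 0.0142 for HNRNPA1 (-0.00378 without DMSO replicate 1, -0.0112 without STM3675 replicate 2), -0.00187 to 0.0167 for KRT18 (-0.00158 without DMSO replicate 2, -0.00187 without STM3675 replicate 2), -0.00867 to 0.0913 for HSP90AA1 102087044 and -0.0153 to 0.0563 for the site with no gene at 94110736. For MAT2A sites they ran from -0.0229 to 0.0273 at 85539201 (-0.0137 without DMSO replicate 1), -0.0574 to 0.101 at 85539202 (-0.0128 without DMSO replicate 1), -0.00462 to 0.0801 at 85543720, -0.0987 to 0.0657 at 85544657 (0.0258 without STM3675 replicate 2) and -0.09 to 0.0153 at 85545066 (0.00263 without STM3675 replicate 2). Camera's direction changed, with no list passing, over DRACH sites for double-stranded RNA sensing (adjusted p = 0.76), interferon-stimulated genes (0.63), cleavage and polyadenylation (0.83) and splicing factors (0.63), and relative to the trend on the DMSO level for RNA surveillance and the cell cycle (0.99 each). Without DMSO replicate 1 it changed for interferon-stimulated genes (0.71, in a range of 0.68 to 0.88 with 1 library left out) and cleavage and polyadenylation (0.97, in a range of 0.82 to 0.98). The cause was not tested.

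Sites that fell in CAOV3 numbered 37161 with 50 reads and 36574 with all 14 libraries in one fit, where fewer sites were tested. Sites that rose numbered 350 with 50 reads, 205 with limma, 239 with 14 libraries, 1710 with Fisher's exact test on pooled counts, 118 among DRACH sites only, 1055 among sites that passed in another line and 3 with the one-sided test. They ranged from 76 to 965 with 1 library left out: 965 and 958 without DMSO replicates 1 and 2, 100 and 76 without STM3675 replicates 1 and 2. Genes that rose numbered 20 with limma, 12 with unweighted means, 3 with DRACH sites only, 18 with sites that passed in another line, and 1 to 32 with 1 library left out: 32 and 31 without DMSO replicates 1 and 2, 3 and 1 without STM3675 replicates 1 and 2. The ratio of mean levels, 0.386, was 0.308 with 50 reads, 0.242 for DRACH sites, 0.288 weighted by coverage, 0.374 for sites that passed in another line, 0.0558 after subtraction of the non-DRACH median and 0.0821 after subtraction of the STM3675 mean of the lowest DRACH class. The replicate numbers do not pair the libraries (correlation of deviations -0.0025 in CAOV3, -0.03 to 0.024 among lines). With the replicate block, 56741 sites and 9172 genes fell, 73 sites and 11 genes rose, 6 of the 10 named rises lost the call, camera's direction for interferon-stimulated genes changed (adjusted p = 0.98) and 27493 sites differed among lines. Antigen presentation passed relative to the trend on the DMSO level (adjusted p = 0.0013, with a smaller fall than that trend), but not otherwise. Ribosomal proteins had adjusted p = 0.18 with an estimated correlation, and epithelial markers 0.51. With 1 library left out the latter ran from 0.014 to 0.09, with 0.068 and 0.09 without DMSO replicates 1 and 2. With 1 library left out, the common dispersion came only from the pair left whole. Beyond this and what fewer tested sites explain, the cause was not tested.

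Sites that differ among lines numbered 11747 with 50 reads, 6688 with limma, 12384 among DRACH sites of 0.25 or more, 6871 among the 4 lines of higher background and 3170 between the 2 of lower background, and, in separate tests of DRACH sites of 0.25 or more, 7795 among those 4 lines and 5288 between those 2. Sites higher in a line numbered 6379 in CAOV3, 1134 in EFO21 and 976 in SKOV3 with 50 reads, and 969 in A549, 5882 in CAOV3, 667 in EFO21 and 322 in SKOV3 among DRACH sites of 0.25 or more. There 1019 were lower in COV644. A library left out also takes its line out of the common dispersion, whose value by line was 2.74 in SKOV3 and 1.23 in OE21. With 1 library left out, sites higher ran from 1002 to 2033 in A549 (1002 and 1026 without its replicates 1 and 2, 1071 without OE21 replicate 2), 6510 to 10889 in CAOV3 (6510 without its replicate 2), 867 to 2964 in COV644 (1137 and 867 without its own), 97 to 369 in OE21 (139 and 97 without its own), 1483 to 5222 in EFO21 and 2343 to 8315 in SKOV3. For EFO21 these were 5222 without its replicate 1, 1922 and 1594 without COV644 replicates 1 and 2, and 1682 and 1483 without those of OE21. For SKOV3 they were 8315 and 2343 without its replicates 1 and 2, 3154 and 2613 without those of COV644, and 2824 and 2519 without those of OE21. Sites lower ran from 468 to 1517 in A549 (468 and 564 without its own), 85 to 232 in CAOV3 (85 without its replicate 1), 558 to 2399 in COV644 (634 and 558), 625 to 1359 in EFO21 (625 and 662), 1164 to 5638 in OE21 (1381 and 1164) and 897 to 1902 in SKOV3 (897 without its replicate 2). The cause was not tested.

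Mean levels in A549, CAOV3, COV644, EFO21, OE21 and SKOV3 were 44.3%, 49%, 45.2%, 44.8%, 41% and 43.9% with 50 reads, and 38.9%, 42.3%, 37.6%, 39.2%, 35% and 38.8% weighted by coverage. At DRACH sites of 0.25 or more they were 57.7%, 63.2%, 60.7%, 58.5%, 55.3% and 57.1%, and 47.1%, 52.2%, 56.3%, 46.1%, 51% and 44.4% after background subtraction. CAOV3 was highest and OE21 lowest under each of these except background subtraction, which lowers the lines of higher background too much. In simulated data of the CAOV3 design 92.9% of the sites that fell in the data were recovered at their observed levels, which had already passed the same test. When 200 sites were changed, 36% of those lowered to 0.25 of their level were recovered. These shares differ in effect size as well as in the number of sites changed. Depth itself was not varied there.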

Other observations

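Tests written before their results were seen were those of neighbouring adenosines and of background at first-exon starts; the other tests in this part were chosen only after the results were seen.

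The 6 ACAGA sites in the last exon of MAT2A, targets of METTL16, varied among lines with DMSO. Their mean was 64% ± 0.05 in A549, 59.3% ± 1.4 in COV644, 49.8% ± 1.6 in OE21, 46.2% ± 0.4 in EFO21 (down to 12 reads at 1 site), 36.3% ± 1.9 in CAOV3 and 32% ± 1.3 in SKOV3. CAOV3, highest of the 6 lines at DRACH sites before background subtraction and below COV644 after it, was among the 2 lowest here. The difference among lines of this mean was not tested.

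DRACH sites with the highest level in other lines kept more A reads after STM3675. Sites at 90% or more had 2.82 times the treated mean of sites at 25% to 50%, where a uniform unconverted background would give about equal means. Non-DRACH adenosines within 25 nt that were under 25% in the other lines gave -1 points between the same classes. The sites themselves gave 15.2 points. Poor conversion of the surrounding RNA was thus not seen at these neighbours. Those at 25% or more, which poorly converted RNA could hold, were left out, so the test cannot exclude it. A hypothesis that stays open is 1 common factor on the odds of methylation, which would leave more at nearly complete sites: the background-corrected odds ratios of the 3 upper classes were 0.0116 ± 0.00016, 0.0103 ± 0.00025 and 0.00893 ± 0.00038, a spread of 1.3 times, but 1.66 times with another background. The choice of background keeps it undecided, and loss of m6A that depends on the age of each RNA was not tested.

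The 13 sites at the start of first or single exons with 50% or more with DMSO and 50 or more reads in every library kept over 0.8 of their level after STM3675; of 66 tested starts at 25% or more, 2 fell, with a ratio of means of 0.901. Unconverted background is argued against: at the 6 of the 13 covered in all 12 DMSO libraries, the level in the 2 lines of lower background was 1.04 times that in the other 4 (69.4% ± 4.3 over 4 libraries and 66.6% ± 3.7 over 8). Nor did first exons as a whole keep their level, since 0.101% of 988 sites farther than 10 nt from the start did. Of the 13, 12 lie at the first annotated nucleotide. No biological explanation was tested, and misreading at transcript ends was not tested either.

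At 69 sites the level differed by 50 points or more among lines. The non-DRACH medians of the DMSO libraries ran only from 3.85% to 14.3%, and background of that size could not give such a range. COV644 or OE21 was lowest at 40.6% of these sites, but their selection by range keeps this share from being a test of background. An A-to-G change on every copy would leave no A, whereas the median of the lowest line at the 44 DRACH sites was 18.7%, with 2 sites under 1%. That median cannot decide the question at a single site, or for a change on only some copies. A base difference beside the adenosine that makes or breaks the motif may account for some: 76% of the 25 non-DRACH sites are 1 base from DRACH, below the 90% the test asked for, and the other 6 are farther than 1 base. Steady non-DRACH sites were at 97.4%, above the variable sites (two-sided Fisher's exact p = 5.3e-05). A share higher than 97.4% could not have passed that test. The comparison could thus only go against the explanation, which leaves it undecided. Whether a base difference breaks the motif in the low line at the 44 DRACH sites was not examined. Lack of C after the adenosine was more frequent at the variable sites (60% against 28.9%, two-sided Fisher's exact p = 0.0014). Of the variable non-DRACH sites at 50% or more in CAOV3, 8 of 8 fell with STM3675 (medians 89.1% and 9.59%). That does not set them apart, as only 19 of 900 non-DRACH sites at 50% or more with 50 reads kept over 0.8 of their level. No genome sequence of these lines was used here.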
